A study of Mus musculus with 15 samples.

How the data were processed

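The series holds 15 samples of striatal RNA from male mice aged 11 weeks, in 3 groups of 5: wild type with LNA-SCB, R6/2 with LNA-SCB and R6/2 with LNA-CTG. Per the labels' protocols, RNA was extracted with the miRNeasy kit, and Cy3-labelled cRNA was made from 100 ng of total RNA with a low-input amplification kit. Each sample was hybridised to 1 array of a mouse design (028005, coordinates on mm9). Spot intensity was extracted with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, per the file headers. Those deposited intensity values include the processed signal, from which the software had already subtracted background, and the flags used below. The authors also deposited a table of log2 values. Its scale was found by setting it against the scanner values: normexp background correction with an offset of 50 followed by quantile scaling gave the same numbers to within 0.000119, so that table and that alternative coincide here. A reference RNA named in the series design was not analysed here.

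The arrays lay on 2 slides. Slide 1 held 3 wild-type, 3 R6/2 LNA-SCB and 2 R6/2 LNA-CTG animals, and slide 2 held 2, 2 and 3. Each array had 59305 non-control spots and 0 saturated spots, with 34410 to 38607 probes well above background. Control spots and spots with an outlier flag were left out, spots of 1 probe were averaged, and 69 probes with no usable spot on at least 1 array were dropped.

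Probes were named through the accessions and symbols of the scanner files against a table of mouse genes of assembly GRCm38.p6, used for names only. Of the distinct probes 31418 matched a gene and 24263 did not. The main values were log2 of the processed signal minus the 75th percentile of the array. A probe was tested if it was well above background on at least 5 of the 15 arrays, whatever their group. This left 24222 named probes of 17338 genes. For the 5413 genes with several tested probes, the brightest over all arrays stood for the gene.

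Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with all 15 arrays in 1 fit of 3 group means. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Where a gene was not well above background on any array of a group, the fold is given as "at least". The bright group's mean was set against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background.

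Before the data were examined, 33 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists cover striatal neurons and interneurons, glia and immune cells, vessels, choroid plexus, blood, neighbouring brain regions, neuronal signalling, stress, clock, metabolic and innate immune pathways, and genes with CAG or polyglutamine tracts. The 32 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. An estimated correlation and fry were alternatives. With the estimated correlation 0 lists were called in all 3 comparisons, and fry called 6, 0 and 6. Median, mean and test direction of a list differed in sign for 6, 3 and 3 lists in the order of the report, of which 0 were called.

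The named genes were, for each comparison, Htt and Gm12695; the 10 largest rises and 10 largest falls by fold among called genes with a symbol and no overlap between groups; up to 4 called members with the largest fold of each list described, or up to 2 with the smallest p where none was called; up to 10 genes called in opposite and up to 5 in the same direction in the disease and oligonucleotide comparisons; and genes with an outlying array. Probes with triplet runs, and D130043K22Rik, were chosen after the data were seen.

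The R6/2 signature held the genes called between wild type and all 10 R6/2 arrays as 1 group. The score of an array was the mean signed log2 deviation from the wild-type mean, tested by an exact permutation over 252 splits. Correlations between comparisons with shared arrays were set beside 100 simulations of unchanged groups, and beside 20 splits of the shared arrays. Runs of triplets were counted in the 60-base probe sequences of the scanner files.

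The fits were tested on simulated data with 200 changed genes of 17338. For R6/2 against wild type under LNA-SCB, 55.6%, 86.8% and 94.3% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 5 false calls. For LNA-CTG against LNA-SCB in R6/2 it was 43.3%, 83.3% and 97.3%, with 7 false calls. For R6/2 with LNA-CTG against wild type it was 47.4%, 77.9% and 92.6%, with 4 false calls.

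Alternatives covered the scaling (normexp with quantile, quantile of the processed signal, median of tested probes, the deposited log2 table), the filter on dim probes, the mean over the probes of a gene, the slide and the replicate number as blocks, each slide alone, each of the 15 arrays left out, only the 2 groups compared, the variance model and the threshold. After the data were seen, 3 more were added: the slide row as a block, probes with at least 4 CAG or CTG units left out, and an exact permutation of list means over arrays.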

Results

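Gene expression was measured with 1-colour Agilent arrays in the striatum of 15 male mice aged 11 weeks. R6/2 mice carry a fragment of the human huntingtin gene with an expanded CAG repeat and are a model of Huntington's disease. The animals had received oligonucleotides built from locked nucleic acid (LNA), which binds RNA tightly. LNA-CTG is complementary to CAG repeats, and LNA-SCB is the oligonucleotide given to the control groups. There were 5 wild-type animals given LNA-SCB, 5 R6/2 animals given LNA-SCB and 5 R6/2 animals given LNA-CTG, with 1 array per animal. On each array between 61.8% and 69.3% of the probes were well above background, and the number of arrays limits the precision. After filtering, 17338 genes were compared. Changes are given on the log2 scale with the standard error of the limma fit (n = 5 per group), and adjusted p-values are Benjamini-Hochberg values over all genes unless a list is named.

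The genotype labels were checked first. Gm12695, the gene at the insertion site of the R6/2 transgene, was not well above background on any wild-type array. It was at least 32.1-fold higher in R6/2 animals given LNA-SCB (5.98 ± 0.27 on the log2 scale, adjusted p = 1.5e-08) and at least 26.8-fold higher in those given LNA-CTG (5.73 ± 0.27, adjusted p = 2.8e-08). Its probe lies on chromosome 4 at 96390578 to 96390637 of the mouse build mm9. The R6/2 groups differed by -0.26 ± 0.27 for this gene (adjusted p = 0.917). The probe for mouse Htt, the endogenous huntingtin gene, lies on chromosome 5 at 35251949 to 35252008. Its values differed by -0.05 ± 0.08 between R6/2 and wild type under LNA-SCB (adjusted p = 0.821) and by 0.08 ± 0.08 between the oligonucleotides (adjusted p = 0.913). The array design gives no probe for the human transgene, so its level was not analysed here.

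The comparison of R6/2 with wild-type animals, both given LNA-SCB, asks what the disease model changed in the striatum. Genes of medium spiny neurons, the main neuron type of the striatum, were lower in R6/2. Pde10a, a phosphodiesterase enriched in these neurons, fell by 1.80 ± 0.15 on the log2 scale (adjusted p = 5.8e-06), and Scn4b, a sodium channel subunit, fell by 2.14 ± 0.16 (adjusted p = 3.0e-06). Markers of the indirect pathway fell too, with Penk, the enkephalin precursor, changing by -1.49 ± 0.19 (adjusted p = 0.000236). In all, 1323 genes changed, 454 higher and 869 lower, and 509 of them changed by at least 1.5-fold.

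Of 31 shared medium spiny neuron markers, 26 were lower and 0 were higher (camera adjusted p = 3.0e-33, adjusted p = 0.119 with an estimated correlation). The largest changes were in the calcium channel Ryr1 (4.52-fold lower), Scn4b (4.40-fold lower), Pde10a (3.49-fold lower) and the signalling regulator Rgs9 (2.62-fold lower). The mean of the list was -0.96 on slide 1 alone and -0.78 on slide 2 alone. Of 10 indirect-pathway markers 7 were lower (camera adjusted p = 9.0e-10, adjusted p = 0.119 with an estimated correlation), among them Upb1 (3.31-fold), the adenosine receptor Adora2a (3.05-fold), Penk (2.81-fold) and Gpr52 (2.54-fold). Of 11 direct-pathway markers 2 were lower, the dopamine receptors Drd1 (2.37-fold) and Drd3 (1.81-fold), and the list as a whole did not pass (camera adjusted p = 0.0854). Adjusted over the list alone, these counts were 30 lower for the shared markers, 8 lower for the indirect pathway, and 5 lower with 1 higher for the direct pathway.

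Genes of neuronal signalling were lower as well. Of 34 potassium, sodium and calcium channel genes 12 fell (camera adjusted p = 1.3e-09, adjusted p = 0.389 with an estimated correlation), led by Kcnh3 (2.62-fold), Kcnh4 (2.13-fold), Kcnip2 (1.79-fold) and Cacnb2 (1.75-fold). Of 32 neurotransmitter receptor genes 14 fell and 1 rose (camera adjusted p = 1.2e-07, adjusted p = 0.488 with an estimated correlation). Gabrd, a GABA receptor subunit, was 2.43-fold lower, the serotonin receptors Htr4 and Htr1b were 2.04-fold and 1.97-fold lower, and the serotonin receptor Htr2c was 2.05-fold higher. The mean of the channel list was -0.41, with -0.56 on slide 1 alone and -0.19 on slide 2 alone. That of the receptor list was -0.37, with -0.46 and -0.22. Of 11 interneuron markers 6 fell (camera adjusted p = 1.2e-07, adjusted p = 0.124 with an estimated correlation), including 3 genes of acetylcholine handling, Slc18a3 (1.76-fold), Chat (1.68-fold) and Slc5a7 (1.66-fold), and Pthlh (1.69-fold).

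Of 19 circadian clock genes 5 fell and 1 rose (camera adjusted p = 0.0036, adjusted p = 0.119 with an estimated correlation). Npas2 was 2.30-fold lower, Hlf 1.46-fold and Dbp 1.37-fold lower, and Nr1d2 was 1.72-fold higher. Of 26 immediate-early and activity-regulated genes 4 fell (camera adjusted p = 0.00454, adjusted p = 0.832 with an estimated correlation), namely Rgs4 (4.12-fold), Homer1 (1.55-fold), Ier5 (1.41-fold) and Per1 (1.37-fold). The mean of that list was -0.47 on slide 1 alone, 0.05 on slide 2 alone and -0.47 without R6/2 LNA-SCB replicate 4.

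Among glial genes, 3 of 20 astrocyte markers fell, the transporters Slc4a4 (1.54-fold) and Slc1a2 (1.40-fold) and the receptor Fgfr3 (1.23-fold; camera adjusted p = 0.0261, adjusted p = 0.832 with an estimated correlation). The astrocyte call ended when any of 4 single arrays was left out, on slide 1 alone (adjusted p = 0.244) and with normexp and quantile scaling (adjusted p = 0.0589). Of 22 oligodendrocyte and myelin genes 2 fell, Tspan2 (1.43-fold) and Cldn11 (1.31-fold; camera adjusted p = 0.035, adjusted p = 0.901 with an estimated correlation). The mean of that list went from -0.16 to -0.08 without R6/2 LNA-SCB replicate 5 (adjusted p = 0.3), and its call ended without any of 3 other arrays too. The list of 35 interferon-stimulated genes had a mean change of 0.28 and 33 positive values (camera adjusted p = 0.035, adjusted p = 0.901 with an estimated correlation), but 0 members passed singly. Among its members Eif2ak2 changed by 0.38 (adjusted p = 0.346). With slide 2 alone the mean was 0.15 (adjusted p = 0.678), and without R6/2 LNA-SCB replicate 2, whose own mean was 1.25, it was 0.0399 (adjusted p = 0.776). The interferon call also ended with the slide row as a block (adjusted p = 0.0765), with normexp and quantile scaling (adjusted p = 0.0589) and without several other single arrays.

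Genes chosen for the size of their change and for groups that did not overlap included several near background in wild type. Onecut1, a developmental transcription factor, was at least 2.66-fold higher in R6/2, Mgarp at least 2.27-fold, Rgs13 at least 1.48-fold and Adamts19 at least 1.35-fold. Plekhs1 and Il17b were about 4.60-fold and 3.08-fold higher, likewise near background, with 1 of 5 wild-type arrays well above it. Tnfrsf13c, Plac9a, Zfhx2os and Sfmbt2 rose by 2.78-fold to 3.15-fold. Among the falls, the growth signal genes Wnt8b and Fgf3 were at least 7.28-fold and at least 3.95-fold lower, and Dgat2l6 was at least 3.70-fold lower. Sec14l3, Odf4 and Nxf7 were lower by about 19.4-fold, 6.44-fold and 5.42-fold, folds without a firm floor because each was well above background on only 1 of 5 R6/2 LNA-SCB arrays. Slc4a11, Tmprss6, Ptprv and Dmkn fell by 5.59-fold to 9.62-fold.

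Of the 17338 genes, 7.98% had groups that did not overlap, where chance gives 0.794%. The count of changed genes was 373 on slide 1 alone and 51 on slide 2 alone, which held 3 and 2 animals of each of these groups. In an exact permutation test over the 10 arrays, a test added after the data were seen, 6 of the 10 lists called by camera passed after adjustment (adjusted p = 0.0363): both medium spiny neuron lists with a call, interneuron, receptor, channel and clock genes.

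**Figure D1:**
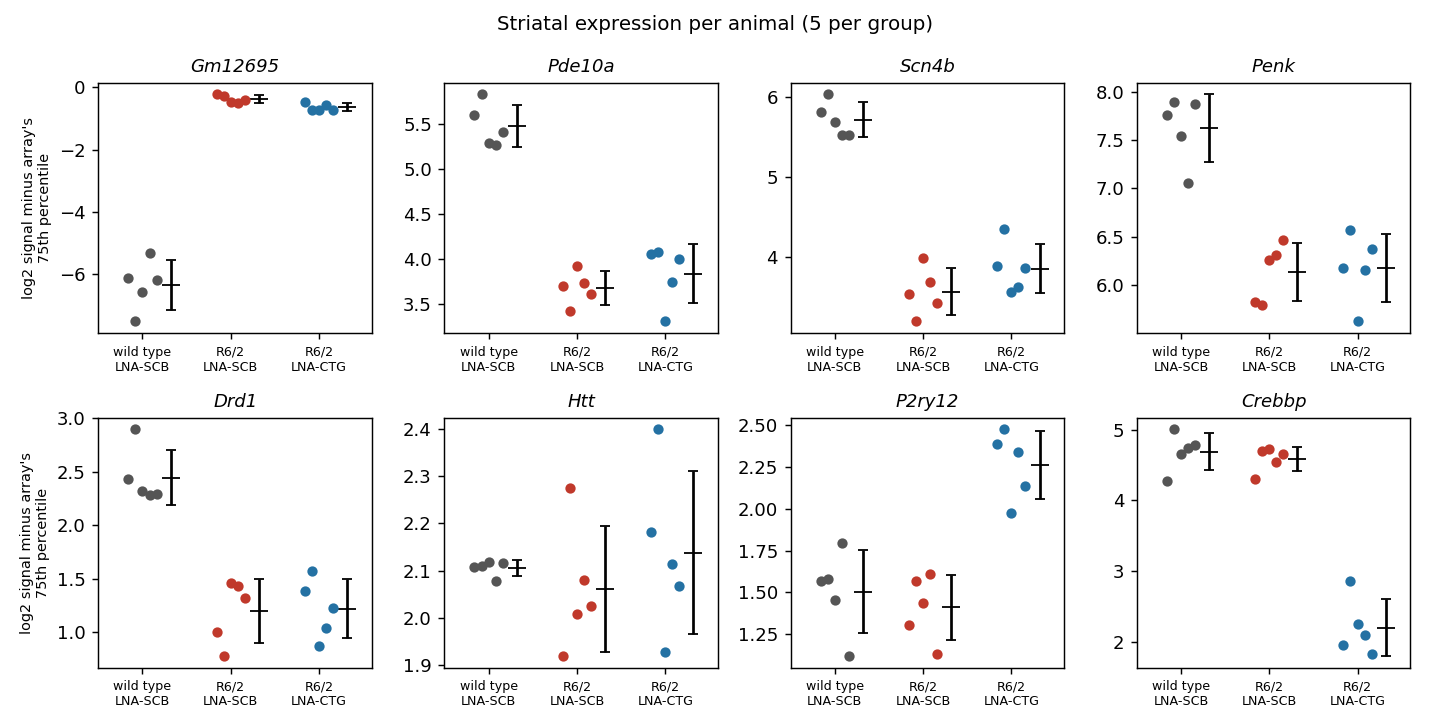
Signal of 8 genes per animal, as log2 of the processed signal minus the 75th percentile of the array, for 5 animals in each of 3 groups; points are animals and bars are the mean and SD. Pde10a, Scn4b, Penk and Drd1 lay lower in both R6/2 groups than in wild type, P2ry12 lay higher and the Crebbp probe lower in R6/2 given LNA-CTG, and Gm12695 was not well above background in wild type.

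The comparison of LNA-CTG with LNA-SCB within R6/2 asks what the oligonucleotide directed at CAG repeats changed. In all, 25 genes changed, 3 higher and 22 lower. P2ry12 and Gpr34, receptors of resting microglia, rose by 0.85 ± 0.13 (adjusted p = 0.00948) and 0.81 ± 0.12 (adjusted p = 0.00874). The largest falls among named symbols were in Pif1, a DNA helicase (fell by 2.64 ± 0.19 on the log2 scale, adjusted p = 2.4e-06), Arhgap17 (fell by 2.56 ± 0.17, adjusted p = 2.2e-06) and Crebbp, a histone acetyltransferase (fell by 2.39 ± 0.17, adjusted p = 2.4e-06). Many of these falls were seen by probes that themselves hold a CAG run, and for Trp63, Arhgap17 and Crebbp, the genes among them with another tested probe, that probe did not fall.

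Pif1 was 6.23-fold, Arhgap17 5.91-fold, Crebbp 5.24-fold, Git2 4.34-fold and Trp63 4.25-fold lower, and each of these 5 probes contains a run of 5 or 6 CAG units. Over all 37487 probes detected, 12 held a run of at least 4 CAG units, 11 of them had a negative change and 9 were among the 30 probes called lower. The mean over these 12 probes differed by -1.65 on the log2 scale between the R6/2 groups (exact permutation, p = 0.00794, the smallest the 252 splits allow; adjusted p = 0.0238 over 6 such tests). It differed by -0.13 between R6/2 and wild type under LNA-SCB (exact permutation, p = 0.341). Among other probes of the same genes, both for Trp63 changed by 0.20 and 0.43, that for Arhgap17 by -0.06 and that for Crebbp by 0.11. Probes of Eif3h, Gm14325 and Smg9 also held 4 CAG units and changed by -0.10, -0.16 and 0.03. The 7 probes with a run of at least 4 CTG units were higher with LNA-CTG by 0.52 (exact permutation, p = 0.0159, adjusted p = 0.0317). For 192 probes with at least 4 units of another triplet the mean differed by 0.08 between the R6/2 groups (exact permutation, p = 0.143). That mean differed by -0.12 between R6/2 and wild type under LNA-SCB (exact permutation, p = 0.00794, adjusted p = 0.0238). The sequence tests were chosen after the called genes had been seen.

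**Figure D2:**
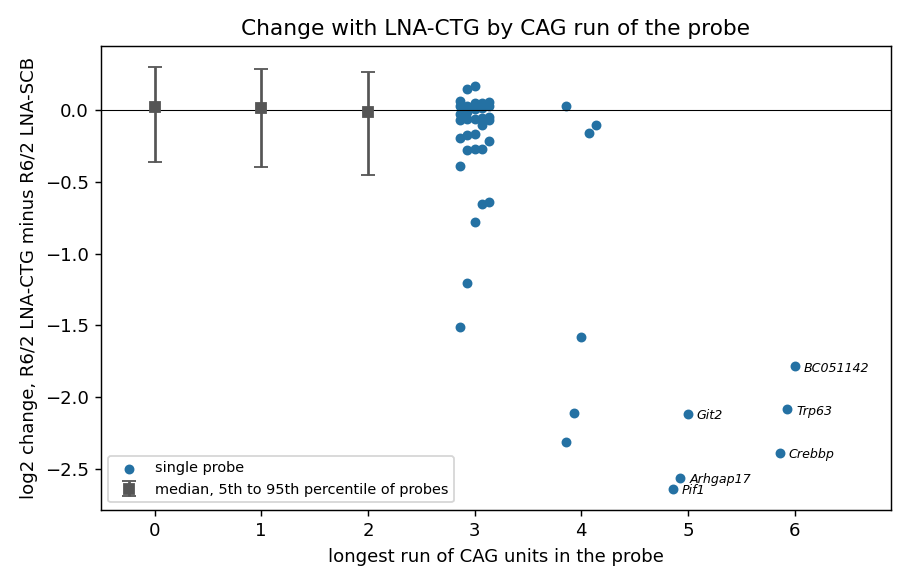
Change of single probes in R6/2 given LNA-CTG against R6/2 given LNA-SCB (log2, vertical axis) by the longest run of CAG units in the probe (horizontal axis); blue points are probes with at least 3 units, and grey squares with bars are the median and the 5th to 95th percentile of the probes with fewer. Of the 12 probes with at least 4 units, 9 were called lower.

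Other genes fell without a CAG run in their probe. Supt20, a transcription cofactor subunit, was 5.09-fold lower and Mdh2, a malate dehydrogenase, 2.85-fold lower. Fabp4, a fatty acid carrier of adipocytes and macrophages, was 3.79-fold lower, Pf4, a platelet chemokine, 3.30-fold lower and Fam83e 2.18-fold lower, while Pde3b, a phosphodiesterase, was 1.48-fold higher. D130043K22Rik, chosen after its values were seen because it has a clone name, showed the largest fall of all (18.5-fold). Fabp4, Pde3b and Pf4 lost their calls in 24, 23 and 21 of 32 alternatives, and Fam83e in 12. Supt20, Fam83e and Pde3b each had another tested probe, dimmer over all arrays, which was not called among the probes detected. Its change is not given here, so these values are those of the brightest probe.

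The activated microglia and macrophage list had a mean change of -0.60 with 24 of 27 members negative (camera adjusted p = 6.0e-08, adjusted p = 0.731 with an estimated correlation), -0.87 on slide 1 and -0.36 on slide 2. The members with the smallest p were Lyz2 (-1.16, adjusted p = 0.295) and Spp1 (-1.44, adjusted p = 0.299), and 0 passed over all genes. Adjusted over the list alone, 8 were lower. The reactive astrocyte list had a mean change of -0.46 (camera adjusted p = 6.1e-08, adjusted p = 0.731 with an estimated correlation), -0.62 on slide 1 and -0.27 on slide 2, and its leading members were Lcn2 (-1.56, adjusted p = 0.248) and C3 (-1.46, adjusted p = 0.358). Homeostatic microglia markers had a mean change of 0.16 (camera adjusted p = 0.00214, adjusted p = 0.826 with an estimated correlation), 0.31 on slide 2 and 0.00 on slide 1. Of the 23 markers 2 were called, and 7 were higher adjusted over the list alone. The list was mixed, with 13 positive and 10 negative values and a median of 0.09. Without R6/2 LNA-CTG replicate 3 that mean was 0.09 and the call ended (adjusted p = 0.207).

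Medium spiny neuron markers had a mean change of 0.17, positive in 30 of 31 genes (camera adjusted p = 8.4e-06, adjusted p = 0.826 with an estimated correlation). None passed singly, the smallest p being those of Adcy5 (0.28, adjusted p = 0.736) and Ppp1r1a (0.29, adjusted p = 0.744). The mean was 0.27 without R6/2 LNA-CTG replicate 3, 0.40 on slide 1 and -0.03 on slide 2, so the difference did not hold within both slides. Markers of neighbouring tissue were not called, but choroid plexus markers (camera adjusted p = 0.548) differed in opposite directions on the 2 slides. They averaged 1.47 with LNA-SCB and -1.02 with LNA-CTG on slide 1, and -0.999 and 1.18 on slide 2, relative to wild type. Cortex markers, not called, had a mean change of -0.68 (camera adjusted p = 0.119). The indirect-pathway list had camera adjusted p = 0.334 and the direct-pathway list 0.0799, with the smallest p of Isl1 (0.26, adjusted p = 0.793) and Eya1 (0.17, adjusted p = 0.837). Immediate-early genes had a mean change of -0.35 (camera adjusted p = 1.0e-05, adjusted p = 0.731 with an estimated correlation), with 0.10 on slide 1, -0.86 on slide 2 and -0.15 without R6/2 LNA-SCB replicate 4. Their leading members were Ier2 (-0.91, adjusted p = 0.114) and Bdnf (-0.62, adjusted p = 0.513).

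A further 5 lists had lower means. Glucocorticoid-responsive genes had -0.22 (camera adjusted p = 0.000336, adjusted p = 0.735 with an estimated correlation), with Nfkbia at -0.47 (adjusted p = 0.34) and Dusp1 at -0.34 (adjusted p = 0.744). Autophagy and lysosome genes had -0.09 (camera adjusted p = 0.0101, adjusted p = 0.731 with an estimated correlation), with Neu1 at -0.18 (adjusted p = 0.439) and Ctsb at -0.26 (adjusted p = 0.744). Endothelial and mural markers had -0.12 (camera adjusted p = 0.0101, adjusted p = 0.735 with an estimated correlation), with Esam at -0.28 (adjusted p = 0.614) and Vwf at -0.53 (adjusted p = 0.62). The calls of these autophagy and endothelial lists each ended on slide 2 alone and without either of 2 single arrays. DNA sensing and Toll-like receptor genes had -0.14 (camera adjusted p = 0.0361, adjusted p = 0.826 with an estimated correlation), -0.33 on slide 1 and 0.07 on slide 2, with Myd88 at -0.34 (adjusted p = 0.681). Without R6/2 LNA-SCB replicate 2 that mean was -0.0247 (adjusted p = 0.867), and the call ended without any of 4 other arrays too. With the replicate number as a block the DNA sensing call also ended (adjusted p = 0.0569). Interferon-stimulated genes had -0.21 (camera adjusted p = 0.0487, adjusted p = 0.826 with an estimated correlation), with Oas3 at -1.21 (adjusted p = 0.667) and Ifitm3 at -0.53 (adjusted p = 0.756). That mean was -0.66 on slide 1, 0.33 on slide 2 and 0.03 without R6/2 LNA-SCB replicate 2. The interferon call also ended with the slide as a block (-0.15, adjusted p = 0.184), with the slide row as a block (adjusted p = 0.117), with normexp and quantile scaling (adjusted p = 0.0545) and without most single arrays. The list of 33 genes with a CAG or polyglutamine tract was not called (mean 0.06, camera adjusted p = 0.334), and its leading members were E2f4 (0.42, adjusted p = 0.734) and Ep400 (0.15, adjusted p = 0.744).

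Over the 10 R6/2 arrays, 0 lists passed the exact permutation test of their means after adjustment. With 252 splits an adjusted p under 0.05 needs at least 6 of the 32 lists with a small p together, so no single list could pass. Unadjusted, the exact p was 0.0238 for endothelial markers, 0.0476 for activated microglia, 0.0476 for reactive astrocytes, 0.198 for medium spiny neuron markers and 0.198 for homeostatic microglia. The number of changed genes depended on single animals and slides: it was 16 without R6/2 LNA-SCB replicate 1 or replicate 4, 15, 16 and 47 without R6/2 LNA-CTG replicates 4, 5 and 3, and 1 and 11 on slides 1 and 2 alone. With normexp background correction and quantile scaling the split was 4 higher and 14 lower.

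**Figure D3:**
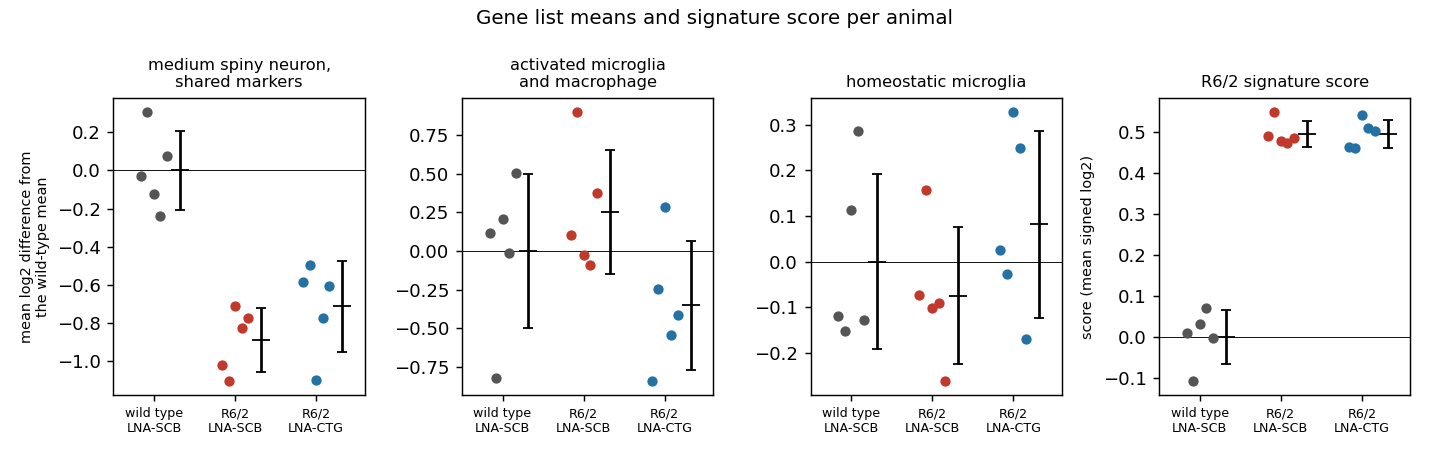
Mean log2 difference from the wild-type mean over the genes of 3 lists, and the R6/2 signature score, for each of 5 animals in 3 groups; points are animals and bars are the mean and SD. The R6/2 groups overlapped in all 4 panels.

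The R6/2 signature asks whether LNA-CTG moved the whole disease profile toward wild type. It held 2177 genes that differed between wild type and all 10 R6/2 animals together, 982 higher and 1195 lower. The mean score was 0.495 ± 0.031 (SD, n = 5) with LNA-SCB and 0.495 ± 0.034 (SD, n = 5) with LNA-CTG. The difference was 0.0006 (95% interval -0.05 to 0.05; two-sided exact permutation, p = 0.976). A signature taken from both R6/2 groups can favour genes on which they do not differ. With signatures from 3 wild-type and 3 R6/2 LNA-SCB animals, scored on the animals left out, the mean difference was -0.10 against a score of 1.22, ranging from -0.31 to 0.13 over 100 splits.

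None of the genes changed by the disease was called in the opposite direction with LNA-CTG (0 by limma, against 0.726 for independent lists and a simulated mean of 0.01). The simulated groups hold no effect, so almost no gene is called in them. Mybpc3, a myosin-binding protein, and Wfikkn1, a protease inhibitor, were lower in R6/2 and lower again with LNA-CTG, by 1.88-fold and 1.78-fold. Across genes, which are not independent replicates, the correlation of both comparisons was -0.30. Groups simulated without any effect, sharing the R6/2 LNA-SCB arrays in the same way, gave a mean of -0.50. The change between R6/2 and wild type had a variance of 0.0966 across genes, beside 0.0417 in the simulation. The correlations are therefore not directly comparable. With the shared arrays split the median was -0.01. The covariance was -0.0234 beside a simulated -0.0209, a difference of -0.0025. Without R6/2 LNA-CTG replicate 3 the count of genes called in opposite directions was 2, and without wild-type replicate 5 it was 1.

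The comparison of R6/2 given LNA-CTG with wild-type animals asks what still differed under the oligonucleotide. Medium spiny neuron genes were again lower, with Scn4b 3.61-fold, Ryr1 3.32-fold, Pde10a 3.13-fold (fell by 1.65 ± 0.15 on the log2 scale) and Rgs9 2.20-fold lower. In all, 1739 genes changed, 793 higher and 946 lower, and 576 of them by at least 1.5-fold. Of these, 970 had changed in the same direction in R6/2 given LNA-SCB and 0 in the opposite one, where independent lists give 68.2 and 64.5. Groups simulated without any effect against the same wild-type arrays shared 0 calls, but almost no gene is called in such groups. That 0 therefore does not show how far the shared wild-type arrays raise the 970. The covariance of the comparisons was 0.0732 beside a simulated 0.0208.

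Of the 31 shared medium spiny neuron markers 19 were lower (camera adjusted p = 6.0e-22, adjusted p = 0.222 with an estimated correlation). Of 10 indirect-pathway markers 7 were lower (camera adjusted p = 7.0e-08, adjusted p = 0.139 with an estimated correlation), with Adora2a 3.08-fold, Upb1 2.97-fold, Penk 2.73-fold and Gpr52 2.27-fold lower. Of 11 direct-pathway markers Drd1 was 2.34-fold lower and Isl1, a transcription factor, 1.62-fold higher (camera adjusted p = 0.537). Of 11 interneuron markers 8 fell (camera adjusted p = 6.8e-08, adjusted p = 0.139 with an estimated correlation), including Pvalb (2.57-fold), Pthlh (1.72-fold), Slc18a3 (1.61-fold) and Cox6a2 (1.57-fold). Of 32 receptors 13 fell and 1 rose (camera adjusted p = 5.6e-06, adjusted p = 0.491 with an estimated correlation), with Htr4 2.38-fold, Gabrd 2.19-fold, Htr1b 2.15-fold and Adra2c 2.09-fold lower. Of 34 channels 8 fell (camera adjusted p = 2.0e-06, adjusted p = 0.491 with an estimated correlation), led by Kcnh3 (2.24-fold), Kcnh4 (1.98-fold), Cacnb2 (1.78-fold) and Kcnq3 (1.68-fold).

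Immediate-early genes were lower in 9 of 26 (camera adjusted p = 6.2e-08, adjusted p = 0.222 with an estimated correlation), among them Rgs4 (3.68-fold), Egr2 (2.29-fold), Dusp1 (1.74-fold) and Ier2 (1.61-fold). Clock genes fell in 4 and rose in 1 of 19 (camera adjusted p = 0.000981, adjusted p = 0.139 with an estimated correlation), with Npas2 1.95-fold, Per1 1.51-fold and Hlf 1.43-fold lower and Nr1d2 1.47-fold higher. Glucocorticoid-responsive genes fell in 3 of 18, Dusp1, Per1 and Klf9 (1.48-fold; camera adjusted p = 0.00011, adjusted p = 0.491 with an estimated correlation). That mean was -0.66 on slide 1 and -0.06 on slide 2, where the call ended (adjusted p = 0.458). Synaptic genes fell in 6 of 24 (camera adjusted p = 0.00521, adjusted p = 0.719 with an estimated correlation), with Nefh 1.72-fold, Homer1 1.5-fold, Shank3 1.39-fold and Ntrk3 1.37-fold lower. That call ended without wild-type replicate 2 (mean -0.15, adjusted p = 0.0879) and on slide 2 alone (adjusted p = 0.0972).

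Of the other lists called, endothelial and mural markers fell in 3 of 23, Abcc9 (1.43-fold), Rgs5 (1.37-fold) and Slc2a1 (1.27-fold; camera adjusted p = 0.00521, adjusted p = 0.491 with an estimated correlation), a call that ended without wild-type replicate 4 (mean -0.17, adjusted p = 0.0545). In the reactive astrocyte list 1 of 27 fell, Fbln5 (1.71-fold; camera adjusted p = 0.00643, adjusted p = 0.719 with an estimated correlation). The mean of that list was -0.33, -0.55 without wild-type replicate 2, which stood apart, and -0.25 on slide 1 alone, where the call ended (adjusted p = 0.0607). Of 22 oligodendrocyte genes 1 fell, Cldn11 (1.45-fold; camera adjusted p = 0.0143, adjusted p = 0.719 with an estimated correlation), and the call ended without any of 3 single arrays and on slide 2 alone (adjusted p = 0.3). The activated microglia list had a mean of -0.35 (camera adjusted p = 0.0428, adjusted p = 0.746 with an estimated correlation), while its only called member, the chemokine Ccl6, was 2.14-fold higher. That call ended when any of 6 single arrays was left out, with a mean of -0.23 without wild-type replicate 5 (adjusted p = 0.203), and the mean was -0.56 without wild-type replicate 2. In the list with a CAG or polyglutamine tract, 3 genes were higher and 2 lower and the list was not called (camera adjusted p = 0.633); the largest changes were in Asxl3 (1.38-fold higher), Kcnn3 (1.38-fold lower), Atxn1 (1.28-fold lower) and Smarca2 (1.21-fold higher).

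Among the genes with the largest changes and no overlap, Wt1, a transcription factor well above background on 3 of 5 wild-type arrays, was about 7.53-fold higher. Onecut1 was at least 2.87-fold, Adamts19 at least 2.01-fold and Rgs13 at least 1.5-fold higher. Plekhs1 (about 4.67-fold; 1 of 5 wild-type arrays well above background), Fyb2 (about 3.07-fold; 2 of 5), Tnfrsf13c (2.94-fold), Sfmbt2 (2.81-fold), Zfhx2os (2.78-fold) and Tdrd5 (2.55-fold) rose. Among the falls, Wnt8b was at least 5.76-fold, Dgat2l6 at least 2.98-fold and Aoc1 at least 1.43-fold lower, the latter well above background on 3 of 5 wild-type arrays. Slc4a11 was 8.74-fold and Tmprss6 6.75-fold lower. Sec14l3 and Fgf3 were lower by about 11.7-fold and 5.81-fold, folds without a firm floor because they were well above background on only 3 and 1 of 5 LNA-CTG arrays. Pif1 (6.71-fold), Arhgap17 (6.45-fold) and Crebbp (5.63-fold) were lower by the probes with CAG runs. The groups did not overlap for 9.25% of genes, where chance gives 0.794%.

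The count of changed genes was 47 on slide 1 alone and 139 on slide 2 alone. By the exact permutation test of list means 5 lists reached the smallest p the splits allow (0.00794), and their adjusted p was 0.0508.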

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

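The tests on list means over arrays, on single slides, on the share of cell types, on neighbouring tissue and on signal and GC content were chosen after the results they concern had been seen; the other tests were written before their own values were seen, although those on triplet runs followed from the genes called.

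Of 225 groups of 5 arrays examined for an array standing apart, 11 had one, where chance gives about 11.25. The R6/2 signature score of R6/2 LNA-SCB replicate 2 was 0.549, the others being 0.472 to 0.490. Htt on wild-type replicate 4 was 2.08, a small step below the others (2.11 to 2.12). Git2 on wild-type replicate 1 was 1.61, below the others (2.12 to 2.29). Mdh2 on R6/2 LNA-CTG replicate 2 was 6.35, above the others (5.04 to 5.16). Tdrd5 on R6/2 LNA-CTG replicate 1 was -2.39, below the others (-2.02 to -1.98).

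Among list means relative to wild type, reactive astrocyte genes stood at -0.87 on wild-type replicate 2 (others 0.06 to 0.36). Lymphocyte and neutrophil markers stood at 1.02 on R6/2 LNA-SCB replicate 2 (others -0.44 to -0.19) and at 0.83 on R6/2 LNA-CTG replicate 3 (others -0.75 to -0.42). Immediate-early genes stood at 0.54 on R6/2 LNA-SCB replicate 4 (others -0.60 to -0.32), unfolded protein response genes at 0.24 on replicate 2 of that group (others -0.13 to -0.04), and developmental homeobox genes at 0.38 on replicate 5 of it (others 0.16 to 0.22).

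Probes with no gene in the reference table were not used in the comparisons. Of 13265 tested, 372 differed between R6/2 and wild type under LNA-SCB (98 higher, 274 lower), 9 between LNA-CTG and LNA-SCB in R6/2 (3 higher, 6 lower), and 424 between R6/2 with LNA-CTG and wild type (202 higher, 222 lower). Of these 209, 6 and 276 were among the 8662 probes for long intergenic RNAs.

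The counts of changed genes were set beside other divisions of the same arrays. In each comparison 1 of 100 splits, the real one, gave as many genes, which argues against a chance division of the arrays: 1323 against at most 20 for R6/2 against wild type, 25 against at most 2 for LNA-CTG against LNA-SCB, and 1739 against at most 782 for LNA-CTG against wild type.

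In R6/2, probes with at least 4 CAG units were lower with LNA-CTG (median -2.10 over 12 probes). Probe signal and GC content are argued against, since that median (-2.10) lies outside the -0.07 to 0.07 of 10000 matched random sets. For this fall, repeats in general are argued against too, since 192 probes with runs of other triplets had a median of 0.11. These 192 probes were not neutral in every comparison. Their mean differed by -0.12 between R6/2 and wild type under LNA-SCB (exact permutation, p = 0.00794, adjusted p = 0.0238). The other probes of 6 genes with a CAG-run probe had a median of 0.0611, but only Trp63, Arhgap17 and Crebbp of the 6 had a CAG-run probe that fell. Their other probes changed by 0.20 ± 0.19 and 0.43 ± 0.48 (Trp63), -0.06 ± 0.10 (Arhgap17) and 0.11 ± 0.13 (Crebbp). These values argue against loss of the whole transcript for these genes. For the other probes that fell, such as those of Pif1 and Git2, no other probe of the gene was tested. Among what stays open is LNA-CTG carried over in the RNA, which could interfere at CAG runs during labelling or hybridisation. Another possibility is an effect in the tissue on the transcript part near the repeat. Neither was tested, nor were other causes or the cause of the rise of the CTG-run probes. D130043K22Rik, Supt20 and Mdh2 fell without a run in the probe, and their transcripts were not searched for repeats.

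By camera the list of medium spiny neuron genes had a higher mean with LNA-CTG and that of activated microglia a lower one, calls that ended with an estimated correlation (adjusted p = 0.826 and 0.731) and in which 0 members passed singly. With the slide as a block the 2 means were 0.19 and -0.65 (larger camera adjusted p = 5.0e-06). These values argue against a shift common to both groups between slides. With single arrays left out the means ranged from 0.12 to 0.27 and from -0.76 to -0.44 (largest camera adjusted p = 0.00598). The direction of neither mean therefore came from 1 animal. These p-values, at the preset correlation, do not measure the spread between animals. For neurons, neighbouring tissue in the dissected sample could account for the difference, which went from 0.17 to 0.0314 with choroid plexus and cortex markers as covariates, as could the spread between animals (unadjusted exact p = 0.198), and the difference was absent on slide 2 (adjusted p = 0.71). For activated microglia the difference held on both slides (larger adjusted p = 0.0423) and was -0.53 with those covariates, but the spread between animals (unadjusted exact p = 0.0476, 1 of 32 lists) and neighbouring tissue (exact permutation with the covariates, p = 0.151) cannot be told apart from an effect with 5 animals per group. A smaller share of other cell types stays open, as does an effect of the oligonucleotide on microglia. The 8 non-neuronal lists tested did not move apart past the largest differences of all splits (exact permutation, p = 0.175). The lists of activated microglia and of reactive astrocytes (mean change -0.46) were not among these 8.

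Gm12695 was higher in R6/2 whichever oligonucleotide was given. For R6/2 against wild type under LNA-SCB, a change of the whole chromosomal neighbourhood is argued against. There the 8 other genes within 1 Mb had a median absolute change of 0.12, below the 95th percentile of matched random sets (0.24). In R6/2 given LNA-CTG these genes differed from wild type by -0.27 (Fggy) to 0.62 (9530080O11Rik), values that were not set beside random sets. A transcript driven by the transgene at its insertion site may be the source, a hypothesis that these arrays leave untested.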

How the results depend on the processing

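The slide row block, the removal of probes with CAG or CTG runs and the permutation of list means were chosen after seeing the data. Of the values of named genes under alternatives, 1749 of 1969, 1098 of 1210 and 1876 of 2128 kept direction and call in R6/2 against wild type, LNA-CTG against LNA-SCB and LNA-CTG against wild type; nearly all of the rest kept direction but lost the call, and 0, 4 and 4 changed direction. Of the list values 305 of 350, 279 of 350 and 405 of 455 kept both. These totals include alternatives that by construction leave the log2 change as it was, such as leaving out an array of the group not compared. They also count the deposited table beside the normexp and quantile scaling with which it coincides. The shares kept are therefore higher than independent alternatives would give. Named genes not called in the main fit, such as Htt, count as kept when they stayed uncalled. Among the called genes alone the share that kept its call is therefore lower than these gene totals give.

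R6/2 against wild type gave 1323 genes, 989 to 1418 with 1 array left out, 373 on slide 1, 51 on slide 2, 568 at adjusted p under 0.01 and 509 with the 1.5-fold limit. The other alternatives stayed within 1.5 times. LNA-CTG against LNA-SCB gave 25, 15 to 47 with 1 array left out, 1 on slide 1, 11 on slide 2, 70 with robust eBayes and array weights, 15 at adjusted p under 0.01 and 14 without CAG-run or CTG-run probes. LNA-CTG against wild type gave 1739, 1198 to 1826 with 1 array left out, 47 on slide 1, 139 on slide 2, 673 at adjusted p under 0.01 and 576 with the 1.5-fold limit. Slides alone and left-out arrays mean fewer samples, and stricter thresholds pass fewer genes. Fewer samples do not account for the rises to 1418, 47 and 1826, each without R6/2 LNA-CTG replicate 3. The cause of these rises and of the rise to 70 was not tested.

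The score difference stayed within -0.01 to 0.02 with 1 array left out (-0.0109 to 0.0152). It lay below 0 with normexp and quantile scaling (-0.00185), the deposited table (-0.00185), no filter (-0.00284), the 15-array filter (-4.0e-05), the mean over probes (-0.00152), the slide block (-0.00412), the replicate block (-0.00446), adjusted p under 0.01 (-0.0173), slide 1 (-0.10, -0.0975) and slide 2 (-0.03, -0.0336), and none of these passed its exact permutation test, which on a single slide, with 10 splits, could not pass. Each of these alternatives picked its own signature genes. With the main signature, slide 1 scores were 0.478 to 0.549 with LNA-SCB and 0.460 to 0.464 with LNA-CTG. On slide 2 they were 0.472 to 0.486 with LNA-SCB and 0.503 to 0.540 with LNA-CTG, the opposite direction. The left-out signature gave -0.10 (-0.101), and the cause was not tested. Genes called in opposite directions numbered 0 to 2 with 1 array left out, 1 with the mean over probes, 1 with the replicate block and 2 with only the groups compared; the cause was not tested.

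For R6/2 against wild type 10 lists were called, 7 to 13 with 1 array left out, 16 on slide 1, 6 with fry and 0 with the estimated correlation. For LNA-CTG against LNA-SCB 10 were called, 7 to 13 with 1 array left out, 17 on slide 1, 6 at adjusted p under 0.01, and 0 with fry, with the estimated correlation and with the permutation of list means. For LNA-CTG against wild type 13 were called, 10 to 15 with 1 array left out, 6 with fry, 0 with the estimated correlation and 0 with the permutation of list means. The permutation could pass only with at least 6 lists of small p together, so its 0 decides nothing about a single list. Estimated correlations were mostly above the preset one, which by construction widens the test.

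List means changed sign within slides: in LNA-CTG against LNA-SCB, immediate-early genes on slide 1 (0.10) and, on slide 2, medium spiny neuron (-0.0279), interferon (0.33) and DNA sensing genes (0.0732); interferon also without R6/2 LNA-SCB replicate 2 (0.0340; lowest -0.49 without R6/2 LNA-CTG replicate 3). Homeostatic microglia on slide 1 had a mean of 0.0048 and a test in the opposite direction, and immediate-early genes in R6/2 against wild type had 0.0494 on slide 2. Dusp1 was 0.10 on slide 1 in LNA-CTG against LNA-SCB. Htt, never called, was -0.0163 on slide 2 in that comparison, and in LNA-CTG against wild type -0.0806 on slide 2 and -0.0333 without R6/2 LNA-CTG replicate 2 (highest 0.08, 0.0846 without R6/2 LNA-CTG replicate 3). The cause was not tested. Without CAG-run probes another probe stood for the gene: Crebbp 0.11 and Trp63 0.20 against LNA-SCB, and Arhgap17 0.0310 and Crebbp 0.0557 against wild type.

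Replicate numbers showed no clear pairing of the samples: same-number deviations correlated from -0.35 to 0.38, and 7 of 15 pairs exceeded 0.1. The median was 0.05 for pairs of the same number and -0.03 for other pairs. Of 15 arrays, 5 correlated best with their own number. These values do not exclude a weak pairing. The replicate block gave 1156, 30 and 1536 genes. The slide block gave 1373, 27 and 1735, and the slide row block 1191, 20 and 1606. Genes below the background limit in a group have only a bound there.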

Other observations

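The gene lists of this part were fixed before the data were examined, and the permutation tests of list means over arrays were chosen after the camera results had been seen.

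Several lists that camera did not call held single genes that changed. In R6/2 given LNA-SCB, 2 of 12 homeobox genes were higher than in wild type, Onecut1 (at least 2.66-fold) and Hoxa7 (1.58-fold), and 0 were lower (camera adjusted p = 0.543). The mean of that list was 0.23 higher, and it passed the exact permutation over arrays (adjusted p = 0.0363), although its median was -0.02 and 7 of its genes were negative. Trib3, a stress-response pseudokinase, was 2.40-fold lower and Ddit4l and Plk2, p53-responsive genes, were 1.78-fold and 1.33-fold lower. Msmo1 and Idi1, enzymes of cholesterol synthesis, were 1.31-fold and 1.15-fold lower (camera adjusted p = 0.163 for the list). Syp, a synaptic vesicle protein, was 1.32-fold higher while Shank3 was 1.63-fold lower (camera adjusted p = 0.0706 for the list). Cd4 was 1.83-fold lower. In the list with CAG or polyglutamine tracts Kcnn3 was 1.32-fold and Atxn1 1.30-fold lower and Vezf1 1.14-fold higher (camera adjusted p = 0.844).

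The remaining lists had these camera adjusted p-values in R6/2 against wild type under LNA-SCB: cortex markers 0.386, thalamus, pallidum and septum 0.793, reactive astrocytes 0.639, homeostatic microglia 0.166, activated microglia 0.176, lymphocytes 0.738, oligodendrocyte precursors 0.609, endothelial and mural cells 0.207, choroid plexus 0.696, blood 0.639, heat shock 0.892, unfolded protein response 0.739, p53 targets 0.704, mitochondrial respiratory chain 0.222, glucocorticoid response 0.0994, DNA sensing 0.263 and autophagy 0.609. In LNA-CTG against LNA-SCB within R6/2 the lists not called had camera adjusted p-values from 0.0799 to 0.913, and in R6/2 with LNA-CTG against wild type from 0.0614 to 0.876.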
